A study of Caenorhabditis elegans with 2 samples.

How the data were processed

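The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) of BED-1, a BED-type zinc finger protein of the nematode Caenorhabditis elegans. Per the labels, the worms carried a CRISPR insertion of enhanced green fluorescent protein with further tags in the endogenous bed-1 gene, chromatin was sheared by sonication, and tagged protein was pulled down with an antibody against green fluorescent protein. Whole worms were collected as young adults, at an age of 63 hours, after synchronisation by starvation of first-stage larvae. The 2 samples were biological replicates of 1 group, so no comparison between groups was possible, and every comparison below is between sets of genomic sites. The labels name a possible control experiment, which was not analysed here.

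For each replicate, and for both replicates together, the authors made a ranked list of peaks and a shorter final list. The ranked lists compared 2 sets of peak calls by the irreproducible discovery rate (IDR), which measures how well the ranks of a peak in both sets go together. Per the file descriptions deposited with the samples, each final list was derived from the alignments and from 1 further file that the ranked lists were not derived from; what that file holds is not given in the sources used here. The aligner, the peak caller and their versions are not given in the sources used here. Peaks were thus called both per sample and on pooled samples. Of the 2 final lists from both replicates, one is named conservative by the authors, and the other, which is larger, served as the main list. In the ranked list behind the conservative one, the compared peaks held 85.1% and 84.9% of the peaks in the ranked lists of replicates 1 and 2 by their coordinates. That list was used for the signal of a peak in each replicate, and it does not say which of its columns is which replicate. In the ranked list behind the main one, the same shares were 15.1% and 0.0%, so the peak sets compared there were other ones, which are not described in the sources used here.

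The signal of a peak is the value the authors deposited for it, with a scale that is not given in the sources used here. It was used only to describe, rank or filter peaks within 1 list. The score the authors gave each peak of a final list is derived from its IDR; the lowest score in the main list was 830, which stands for an IDR of 0.01. The deposited ranked lists give the −log10 of the global IDR per peak, and peaks at or under an IDR of 0.01 were taken as passing. Peaks of the ranked list behind the main one with a higher IDR, called failing peaks here, were the background of the tests. Passing peaks that the authors left out of the main list entered neither side. No read counts were in the files used here, so the depth is unknown, and no precision that depends on it is given. The intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting of peaks only.

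Coordinates are 1-based and in the genome build ce11, which is WBcel235; the chromosome lengths of the reference held every peak. Genes came from Ensembl release 115, and the amino acid of each tRNA gene came from the RefSeq annotation of the same assembly, matched by coordinates for 607 of 612 genes. Each summit was put in the first class that held it, in the order promoter (500 bases upstream to 200 downstream of a start of a protein-coding gene), 5' UTR, coding exon, 3' UTR, intron, non-coding gene and intergenic. A summit was called near a non-coding RNA gene within 200 bases of it. A summit was assigned to the protein-coding gene with the nearest start within 1000 bases. The 23 gene lists were set by gene symbol: ribosomal proteins, translation factors and tRNA synthetases, histones, cuticle collagens, vitellogenins, major sperm proteins, chaperones, nuclear hormone receptors, other transcription factors, muscle, neurons, intestine, epidermis and seam, germline and oocyte, cell cycle and DNA replication, proteasome and ubiquitin, mitochondrial respiration and ribosome, splicing and RNA processing, chromatin regulators, innate immunity, detoxification, vulval and developmental signalling, and insulin and lifespan.

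Shares were compared by Fisher's exact test with both sides counted, and the values of a family (7 classes, 7 kinds of non-coding RNA gene, 6 chromosomes, 23 gene lists or 13 sequence motifs) were adjusted by the method of Benjamini and Hochberg, with 0.05 as the threshold. Medians of signal and of GC content were compared by permutation tests with 100000 resamples, on both sides. GC content was taken over 200 bases around the summit. Motifs were sought on either strand within 100 bases of the summit, against up to 10 failing peaks per main peak drawn from the same class and the same 2% bin of GC content, 5877 in all. Words of 8 bases present in at least 10 windows were sought on chromosomes I, III and V by a one-sided Fisher's exact test, and those past the adjusted threshold were tested again on chromosomes II, IV and X. The rank correlation of signal between replicates has a bootstrap interval from 1000 resamples of peaks. Copies of sequence were measured as the share of a window's words of 31 bases that occur once in the genome; a window with a share of 90% or more is called unique here. Main peaks of similar sequence were grouped by BLAST 2.17.0 with an e-value of 1e-05 and a word size of 11. The other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

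The genes named were fixed by a rule: those assigned to the 25 main sites of highest signal, with sites that had no gene named by position, up to 4 genes of highest signal in each list past its test, and bed-1, bed-2 and bed-3. The samples, the main list, the tests, the lists of genes and motifs, the rule and most alternatives were chosen before the data were examined. Those alternatives were the conservative list, all passing peaks with those the authors left out, each replicate's own list, other overlaps, promoter limits, windows, word lengths and backgrounds, and the chromosomes of the word search swapped. Chosen after seeing the data were an IDR of 0.001, the weaker of 2 overlapping main peaks dropped, the 5000 failing peaks of highest signal as background for results other than the promoter share, only windows of unique sequence, peaks near non-coding RNA genes left out, correlations across main peaks with a signal over 100 and across conservative peaks, and other non-coding RNA genes counted only where no tRNA, snoRNA or snRNA gene was near as well.

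The procedures were tested on simulated data before use. In sets of 589 peaks drawn from the failing peaks, with nothing changed, 0 of 140 class tests, 2 of 120 chromosome tests, 0 of 140 tests of non-coding RNA genes, 0 of 460 gene list tests and 1 of 260 motif tests passed. Planted tRNA sites and planted ribosomal protein sites were each called in 20 of 20 sets. A word planted in 10% of the windows was found in 5 of 5 sets, and one planted in 3% in 2 of 5. For GC content, 1 of 20 unchanged sets and 20 of 20 shifted sets were called, and 1 of 20 unchanged splits passed for the signal. The unchanged sets had the signal and GC content of failing peaks. They therefore could not show whether differences of main peaks in signal, GC content or sequence copies lead to calls.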

Results

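BED-1 carries a BED-type zinc finger, a DNA-binding fold found in chromatin proteins and in transposases of many animals. Its sites were mapped by ChIP-seq in whole young adult worms of 63 hours, in 2 biological replicates of 1 group, which give no group comparison. The comparisons below therefore ask where in the genome the sites lay and how alike the replicates were. Peaks were called per sample and on pooled samples, and the signal of each peak is the authors' own value, used here only within a list. The main list, from both replicates, held 589 peaks with a median width of 260 bases, covering 148868 bases. Their median signal was 77.9 (interquartile range 70.8 to 90.6), against 23.4 for the 119933 failing peaks of the same ranked list, and ranged from 2.43 to 783. The conservative list held 523 peaks, and the replicates' own lists held 91 and 99 peaks. The depth is unknown. Tests across peaks treat genomic sites as the units, which are not independent replicates of the experiment.

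The strongest site lay on chromosome IV at 4725465 to 4725687, with its summit at 4725567 in intergenic sequence and a signal of 783, and its neighbour at IV 4728035 had the next highest signal, 408. The first of these summits lay 113 bases before the first base of a short non-coding RNA gene, and IV 4728035 lay within 200 bases of a pseudogene. Sites at small nucleolar RNA (snoRNA) genes followed. The summit at V 12303636 (signal 348) lay in an intron of frm-7, which encodes a FERM domain protein, beside the snoRNA genes C51F7.3 and C51F7.4. The summit at V 8500576 (signal 281) lay in an intron of pxn-1, which encodes a peroxidasin of the extracellular matrix, beside the snoRNA gene ZK994.7. The strongest promoter sites were those of F44E5.4, an Hsp70 family chaperone (II 11759329 to 11759588, signal 272, summit 148 bases upstream of the start), and of rpl-3, a protein of the large ribosomal subunit (III 3867516 to 3867626, signal 255, summit 309 bases upstream). A further site lay at rpr-1, the gene of the RNA of ribonuclease P, the enzyme that trims tRNA precursors, inside an intron of ints-8, an Integrator complex gene (I 13463933, signal 195).

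Of the 25 sites of highest signal, which spanned 152 to 783, 14 were intergenic, 6 intronic, 5 in promoters and 0 in coding exons. Within 200 bases, 4 of the 25 had a snoRNA gene and 0 had a tRNA gene. A protein-coding start lay within 1000 bases of 10 of them. Besides F44E5.4, rpl-3 and ints-8, K08F11.1 had the summit at IV 4725567, 421 bases past its start but outside the gene. For rpa-2, a replication protein A subunit gene, a summit lay 662 bases upstream (I 4769630, signal 251, intergenic). The next in signal were mog-4, which encodes a helicase of splicing and of the switch from sperm to oocytes (II 14561860, signal 195, promoter), tasp-1, a taspase gene (III 10759251, signal 194, promoter), and C46C2.7 (IV 9196438, signal 175, intergenic). The remaining 2 were cbp-1, the CBP/p300 acetyltransferase gene (III 9765637, signal 162, 872 bases upstream, intergenic), and pck-2, a phosphoenolpyruvate carboxykinase gene (I 7869120, signal 152, promoter). The other intronic sites were in cmk-1, a calmodulin-dependent kinase gene (IV 1831382, signal 241), in cutl-18, a cuticlin-like gene, beside the snoRNA gene T03F7.8 (V 11314187, signal 187), and in epg-9, an autophagy gene (IV 2602149, signal 155). The other sites lay in intergenic sequence with no start within 1000 bases, at X 1375275 (signal 209), II 11960822 beside the snoRNA gene W03C9.9 (signal 200), III 2497992 (181), IV 15896071 (164), V 18712268 (162), V 14055238 (157), III 2499478 (155), X 11094201 (152) and II 4048036 (152). Windows of unique sequence surrounded 12 of the 25 summits. The sequence around the strongest summit was unique for 48.8% of its 31-base words. The shares were 41.8% at IV 4728035, 31.2% near rpa-2, 31.8% in cmk-1, 55.9% at mog-4, 51.2% near C46C2.7, 39.4% at pck-2, 14.1% at X 1375275, 12.9% at IV 15896071, 2.35% at III 2499478 and 0% at III 2497992. Higher shares, still short of unique, were 86.5% at V 18712268 and 70.6% at II 4048036.

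Genes of short structural RNAs stood out among the main peaks. A tRNA gene lay within 200 bases of 63 of the 589 summits (10.7%, interval 8.32 to 13.5), against 484 of the 119933 failing peaks (0.404%). snoRNA genes, whose products guide the modification of ribosomal RNA, lay beside 31 main summits (5.26%, 3.60 to 7.39) and 0.218% of failing peaks. snRNA genes, which encode RNAs of the spliceosome and of trans-splicing, lay beside 8 (1.36%) and 0.0834%. The snRNA genes included the spliced leader genes sls-2.4 (signal 119.6 at I 4172248), sls-2.1 (92.7 at II 5844813), sls-2.15 (88.9 at III 11091190) and sls-2.2 (76.6 at II 5543650), named here after their values were seen. The sites at sls-2.4, sls-2.1 and sls-2.2 were similar in sequence. The 8 peaks include a weak one (signal 24.1) that overlaps the peak at sls-2.2 and is likely not a separate site.

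The odds ratio was 29.6 for tRNA genes (Fisher's exact test, adjusted p = 2.8e-64), 25.4 for snoRNA genes (exact test, adjusted p = 5.2e-31) and 16.5 for snRNA genes (exact test, adjusted p = 1.2e-07). Many of the 63 peaks at tRNA genes were similar in sequence to one another, with 12 of them in the largest such group. Such peaks are not independent, so the p-values for tRNA genes, here and below, are likely too small. Other non-coding RNA genes lay near 106 main peaks (17.997%) and 4.63% of failing peaks (odds ratio 4.52, exact test, adjusted p = 5.3e-32). Only 50 of these 106 had no tRNA, snoRNA or snRNA gene within 200 bases as well, and counting those alone the odds ratio was 2.05 (8.49% against 4.33%, exact test, adjusted p = 1.7e-05). The 4 main peaks at microRNA genes were at mir-80, mir-266, mir-51 and mir-52 (0.679% against 0.139%, exact test, adjusted p = 0.0119). Genes of piRNAs, small RNAs of the germline, were rarer at main peaks, with 2 peaks (0.340% against 1.72%, exact test, adjusted p = 0.00807), and ribosomal RNA genes had 0 main and 4 failing peaks (exact test, adjusted p = 1). With the passing peaks the authors left out kept, ribosomal RNA genes did pass, with 2 of 704 peaks (odds ratio 85.4, exact test, adjusted p = 0.000703). Against only the 5000 failing peaks of highest signal the odds ratio was 4.56 for tRNA genes, 6.56 for snoRNA genes, 4.04 for snRNA genes and 2.54 for other non-coding RNA genes, and those of microRNA and piRNA genes no longer passed (exact tests, adjusted p = 0.0725 and 0.497). Neither passed in replicate 2's list (exact tests, adjusted p = 0.205 and 0.484) or at an IDR of 0.001 (1 and 0.572), nor did piRNA genes in replicate 1's (0.477). Only 5 of the 63 windows near tRNA genes were of unique sequence; among unique windows the odds ratio was 8.58 for tRNA genes and 37.1 for snoRNA genes.

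**Figure D1:**
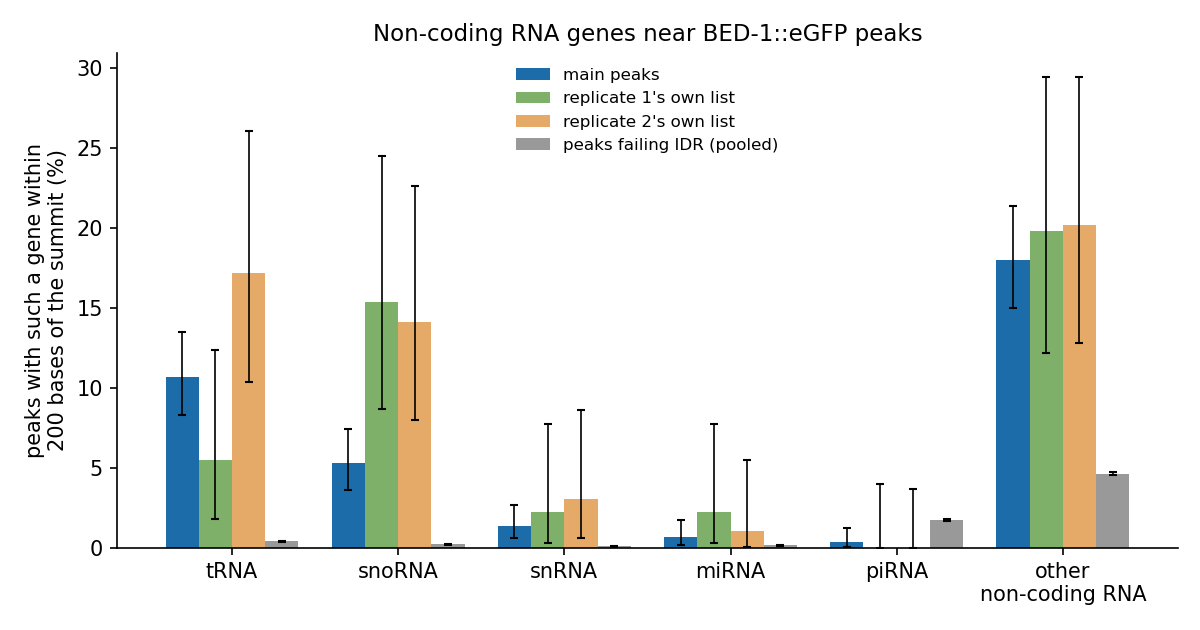
Bars give the share of peaks, in percent, with a gene of each kind of non-coding RNA within 200 bases of the summit, for the 589 main peaks, the lists of replicate 1 (91 peaks) and replicate 2 (99 peaks) and the 119933 failing peaks; error bars are exact 95% Clopper-Pearson intervals. At tRNA genes the main list stands at 10.7%, replicate 1 at 5.49%, replicate 2 at 17.2% and failing peaks at 0.404%.

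By gene, 72 of 612 tRNA genes (11.8%, 9.32 to 14.6) had a main summit within 200 bases, over 18 amino acid products. Genes of tRNA-Ala, with 11 of 34 (32.4%), had main summits more often than the other tRNA genes (odds ratio 4.05, Fisher's exact test, adjusted p = 0.0191), while tRNA-Gly, with 13 of 55 (23.6%), and tRNA-Arg, with 9 of 44 (20.5%), did not pass (exact tests, adjusted p = 0.0859 and 0.585). Summits lay close to the start of the tRNA genes, at a median of 12 bases after the first base (interquartile range -9 to 46), in genes of a median length of 72 bases. The strongest tRNA site, at X 9743667 between a pair of tRNA-Ala genes, had a signal of 150. Main peaks at tRNA genes had a median signal of 83.4 against 77.2 for the other main peaks, a difference of 6.23 (permutation test, p = 0.00969). These tests of the tRNA genes were chosen after the enrichment was seen. The tests by amino acid counted genes, but the 72 genes shared 63 peaks, and many tRNA sites were similar in sequence. The genes are thus not independent units, and those p-values are likely too small.

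Both replicates' own lists had these genes. In replicate 1, 5 of 91 peaks (5.49%) lay at tRNA genes and 14 (15.4%) at snoRNA genes, with odds ratios of 8.13 and 58.3 against its own failing peaks (exact tests, adjusted p = 0.00121 and 8.1e-19). In replicate 2, 17 of 99 peaks (17.2%) lay at tRNA genes and 14 (14.1%) at snoRNA genes, with odds ratios of 31.6 and 51.9 (exact tests, adjusted p = 1.7e-18 for both). The 2 lists share peaks and come from 1 sample each, so their shares were not tested against each other.

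Promoters of protein-coding genes and non-coding genes held more of the main peaks than of the failing peaks, and coding exons and introns held fewer. Coding exons, which held 26.8% of failing peaks, held 89 main peaks (15.1%, 12.3 to 18.3; odds ratio 0.486, Fisher's exact test, adjusted p = 1.2e-10). Promoters held 144 main peaks (24.4%, 21.03 to 28.13) against 16.9% of failing peaks (odds ratio 1.59, exact test, p = 3.4e-06, adjusted p = 8e-06 over the classes). Non-coding genes held 59 (10.02%, 7.71 to 12.7) against 3.96% (odds ratio 2.70, exact test, adjusted p = 6.9e-10), and introns held 21.4% against 26.4% (odds ratio 0.758, exact test, adjusted p = 0.00988). Intergenic sequence held 150 peaks (25.5% against 22.99%, exact test, adjusted p = 0.196), 3' UTRs held 19 (3.23% against 2.33%, exact test, adjusted p = 0.196) and 5' UTRs held 2 (0.340% against 0.596%, exact test, adjusted p = 0.593), none of which passed. Intergenic sequence did pass in 6 alternatives: replicate 2's list (43.4% against 21.8%, odds ratio 2.76), replicate 1's (40.7%, 2.47), an IDR of 0.001 (45.1%, 2.75), the passing peaks the authors left out kept (36.4%, 1.91), the 5000 strongest failing peaks (25.5% against 19.98%, 1.37) and no peaks near non-coding RNA genes (28.6%, 1.36; exact tests, adjusted p from 5.6e-15 to 0.00848). Among unique windows it did not (19.5% against 21.4%, odds ratio 0.890, exact test, adjusted p = 0.454). The promoter share did not pass in the shorter lists of replicate 1 (odds ratio 1.33, exact test, p = 0.269) and replicate 2 (odds ratio 1.24, exact test, p = 0.421) or at an IDR of 0.001 (odds ratio 1.58, exact test, p = 0.0769). The non-coding class did not pass among unique windows (odds ratio 1.53, exact test, adjusted p = 0.0958) or at an IDR of 0.001 (odds ratio 2.26, exact test, adjusted p = 0.103), and introns did not against the 5000 strongest failing peaks (odds ratio 0.935, exact test, adjusted p = 0.581), in either replicate's own list or at an IDR of 0.001.

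**Figure D2:**
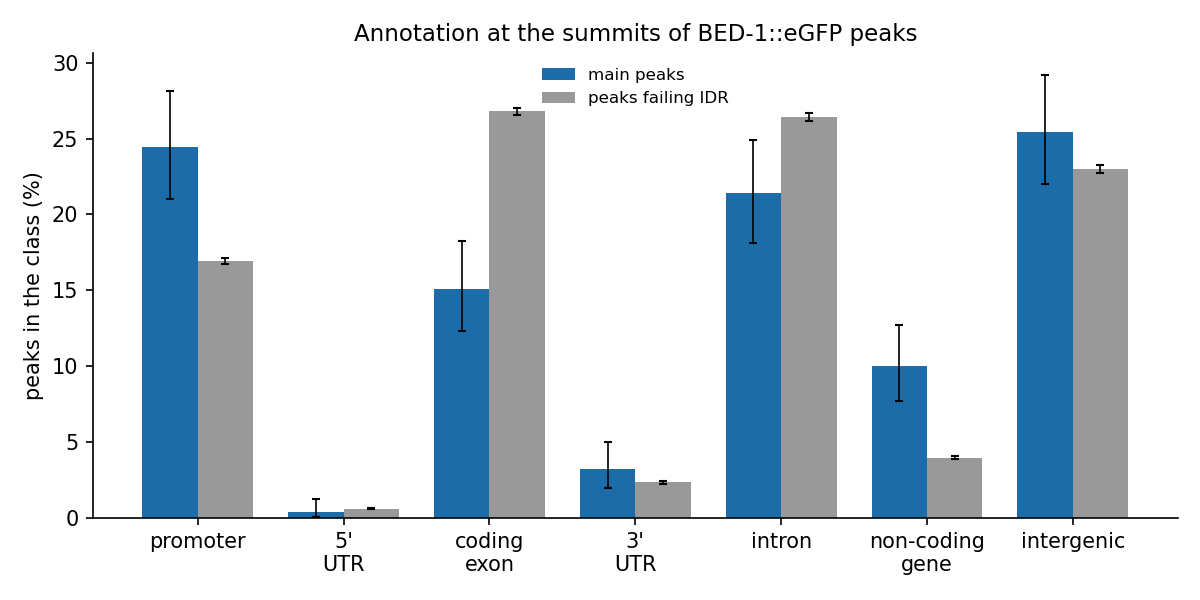
Share of peaks, in percent, whose summit lay in each annotation class, for the 589 main and the 119933 failing peaks; error bars are exact 95% Clopper-Pearson intervals. Coding exons stand at 15.1% of main against 26.8% of failing peaks, and promoters at 24.4% against 16.9%.

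Ribosomal protein genes were the group of protein-coding genes that stood out. Sites lay upstream of rpl-3 (signal 255), rpl-15 (IV 654929, signal 145, 353 bases upstream) and rpl-35 (III 7854698, signal 116, 436 bases upstream), which encode proteins of the large subunit, and of rps-24, of the small subunit (IV 385533, signal 111, 354 bases upstream), all in promoters. The window at rps-24 was unique for 48.2% of its words. The other members were rpl-7A, with a summit in its promoter, rps-11 and rpl-18, with summits in coding exons, and rps-6, rps-15 and rps-8. Summits of rps-6, rps-15 and rps-8 lay in intergenic sequence past the 3' end of the gene, 785, 707 and 761 bases downstream of the start. In all, 262 protein-coding genes were assigned a main peak and 17420 had failing peaks only; ribosomal proteins made up 10 of the former (3.82%, 1.85 to 6.91) and 64 of the latter (0.367%), an odds ratio of 10.8 (Fisher's exact test, adjusted p = 3.1e-06 over 23 lists). Replicate 2's own list held 5 of these genes (odds ratio 28.3, exact test, adjusted p = 5e-05), and replicate 1's held rpl-3 and rpl-15 alone (odds ratio 10.6, exact test, adjusted p = 0.289). Against genes of the 5000 strongest failing peaks the odds ratio was 3.33 and did not pass (exact test, adjusted p = 0.0776).

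Of the other 22 lists none passed. Splicing and RNA processing, with rsp-8, hrpa-1, ddx-23, suf-1 and lsm-7, came nearest (5 genes, odds ratio 3.83, Fisher's exact test, p = 0.0124, adjusted p = 0.143), and passed once peaks near non-coding RNA genes were left out (odds ratio 5.16, exact test, adjusted p = 0.0438). The cell cycle list had 4 genes, among them rpa-2 and mcm-4, a subunit of the replicative helicase (exact test, adjusted p = 0.471). The vitellogenin list had vit-2, a yolk protein gene (exact test, adjusted p = 0.493). There were 6 genes of innate immunity and 4 nuclear hormone receptors. There were 3 each of cuticle collagens, other transcription factors, germline and oocyte, proteasome and ubiquitin, mitochondrial respiration and ribosome, chromatin regulators, and insulin and lifespan. There were 2 each of epidermis and seam, detoxification, and vulval signalling, 1 each of histones, chaperones, muscle and neurons, and 0 each of translation factors, major sperm proteins and intestine (exact tests, adjusted p from 0.493 to 1). Members of these lists were named after their values were seen. Being set by symbol, the chaperone list left out F44E5.4 and the splicing list left out mog-4, both described above. The counts of these lists are thus incomplete, and how many background genes they missed is not known.

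The bed genes themselves had no main peak within 1000 bases of a start. For bed-1 (V 19119527 to 19124922, minus strand), the tagged gene, the nearest main summit was at V 19126055, 1133 bases from a start and inside a tRNA-Phe gene, and the strongest of 2 ranked peaks within 1000 bases had a signal of 14.4. For bed-2 (III 11463665 to 11470808) the nearest main summit was 31614 bases away, and for bed-3 (IV 9916524 to 9921967), which is known for roles in moulting and vulval development, 407169 bases away. Their strongest ranked peaks had signals of 40.4 and 51.5 and failed the IDR threshold.

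Across chromosomes, V held fewer of the main peaks than of the failing peaks, with 97 (16.5%, 13.6 to 19.7) against 21.7% (odds ratio 0.711, Fisher's exact test, adjusted p = 0.0111). X held 121 (20.5% against 19.3%), IV 105 (17.8% against 15.2%), II 98 (16.6% against 15.8%), III 91 (15.4% against 13.7%) and I 77 (13.1% against 14.3%), with none past the test (exact tests, adjusted p from 0.255 to 0.611). On the autosomes 335 of 468 main peaks (71.6%, 67.3 to 75.6) lay outside the middle one of 3 equal parts of a chromosome, against 67.2% of failing peaks (odds ratio 1.23, exact test, p = 0.0482). V did not pass with the conservative list (odds ratio 0.772, exact test, adjusted p = 0.152), either replicate's own list, an IDR of 0.001, the 5000 strongest failing peaks or unique windows. The outer parts passed in only 1 of 9 alternatives, without peaks near non-coding RNA genes (odds ratio 1.52, exact test, p = 0.000502), and had odds ratios from 1.00 to 1.46 in the others.

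**Figure D3:**
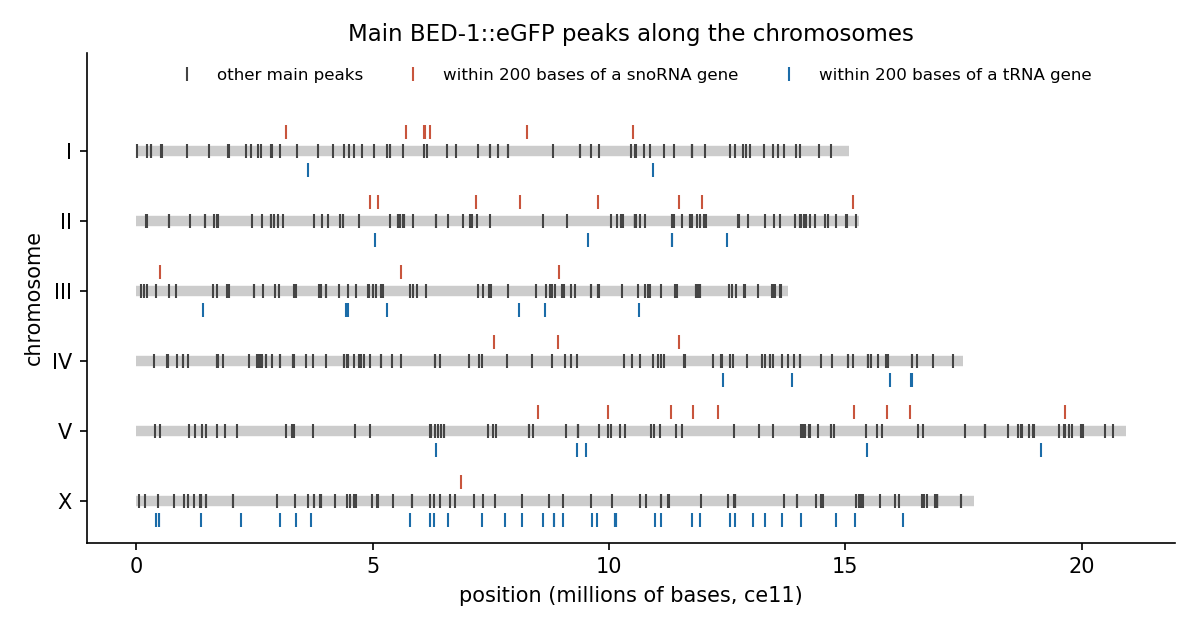
Position of the 589 main peaks along the 6 chromosomes, in megabases of ce11, with 1 tick per peak: blue ticks below the line are within 200 bases of a tRNA gene, red ticks above it of a snoRNA gene, and black ticks on the line are the others. Of the 63 main peaks at tRNA genes many stand on X, where 45 of 276 tRNA genes had a main summit.

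Sequences bound by BED zinc fingers of other animals were sought around the summits. TCGCGA, the core of the palindrome bound by human ZBED1, lay within 100 bases of 29 main summits (4.92%, 3.32 to 6.99) and of 140 of 5877 failing peaks matched for class and GC content (2.38%), an odds ratio of 2.12 (Fisher's exact test, adjusted p = 0.0122 over 13 motifs). The longer ZBED1 palindrome was found at 1 main and 6 failing peaks (exact test, adjusted p = 0.705), the DRE site of Drosophila DREF at 0 and 11 (exact test, adjusted p = 0.766), and the CGATA core of Drosophila BEAF-32 at 17.3% and 18.6% (exact test, adjusted p = 0.705). None of the other 9 motifs passed; the nearest were GATA sites (7.98% against 10.7%) and an element of worm promoters, CTGCGTCT (4.92% against 3.34%), both with an adjusted p of 0.211 by the exact test. TCGCGA did not pass against the 5000 strongest failing peaks (odds ratio 1.73, exact test, adjusted p = 0.0674), where CTGCGTCT did (4.92% against 2.62%, odds ratio 1.93, exact test, adjusted p = 0.0467). Nor did it with the conservative list (odds ratio 1.69, exact test, adjusted p = 0.208), with either replicate's own list, at an IDR of 0.001, or in windows of 50 or 200 bases (odds ratios 1.96 and 1.43, exact tests, adjusted p = 0.202 and 0.271). The replicates' lists held 91 and 99 peaks and an IDR of 0.001 left 82, so the loss of the call there does not show a smaller odds ratio.

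Of 24346 words of 8 bases, 8 passed on chromosomes I, III and V, and 2 of these passed again on II, IV and X. GAATTGAA was in 19 of 324 main windows there (5.86%) against 2.24% of matched failing peaks (one-sided Fisher's exact test, adjusted p = 0.00374), and AAGGATCA in 8 (2.47%) against 0.502% (exact test, adjusted p = 0.00407). Windows that were not unique held 22 of the 40 main peaks with GAATTGAA and 13 of the 21 with AAGGATCA, and 9 and 0 of them lay at tRNA genes. No word passed with the weaker of overlapping peaks dropped, without peaks near non-coding RNA genes, at an IDR of 0.001 or with unique windows only. With the chromosomes swapped, 20 words passed, and neither of these was among them.

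The sequence around main summits had a median GC content of 46% (interquartile range 41 to 51) against 38% (33.5 to 43) for failing peaks, a difference of 8 points (permutation test, p = 1e-05, the smallest these permutations can give). Against the 5000 strongest failing peaks the difference was 2.5 points (permutation test, p = 1e-05, likewise the smallest). The signal of promoter peaks did not differ detectably from that of the others, with a median of 77.9 for the 144 promoter peaks and 77.9 for the other 445, a difference of 0.0110 (permutation test, p = 0.999).

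The replicates shared about as many peaks as not. Of the 91 peaks of replicate 1, 48 (52.7%, 42.001 to 63.310) overlapped a peak of replicate 2 by at least 1 base, and of the 99 of replicate 2, 49 (49.5%, 39.3 to 59.7) overlapped one of replicate 1. The main list overlapped 85 (93.4%) and 96 (96.97%) of them. Among the 1000 strongest ranked peaks of the other replicate, 76.9% and 77.8% had a partner. In the other direction, 86 (14.6%) and 97 (16.5%) of the 589 main peaks overlapped a peak in the shorter lists of replicates 1 and 2. A conservative peak overlapped 406 main peaks (68.9%), and 400 of the 523 conservative peaks (76.5%) overlapped a main one. At the strongest site, IV 4725567, the signals were 371 and 413, and at rpl-3 they were 139 and 105. Across the 586 main peaks found in the ranked list of both replicates, the signals had medians of 37.6 and 42.4 and a Spearman correlation of 0.105 (bootstrap interval 0.0123 to 0.205), a value across genomic features that are not independent replicates. Across those with a signal over 100, it was 0.398 (0.211 to 0.563), across conservative peaks 0.162 (0.0621 to 0.254), across all ranked peaks 0.252, and as Pearson's r of log2 signal in main peaks 0.329. The main signal was a median of 1.002 times the sum of both replicates' signals. Main peaks were chosen by IDR and not directly on this sum. Selecting peaks on such a sum can lower their correlation, but whether it did so here was not tested. The value of 0.105 alone therefore does not tell how alike the replicates were.

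**Figure D4:**
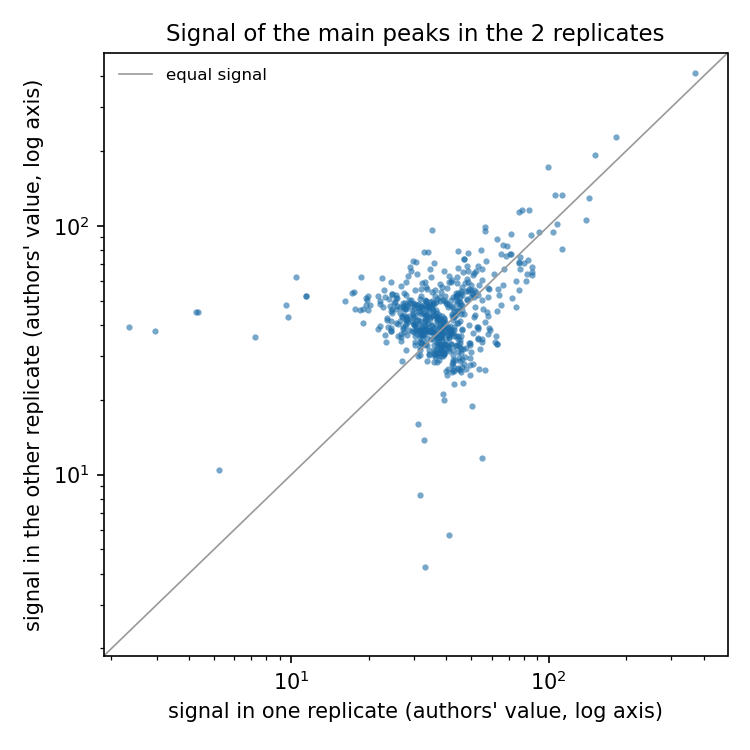
Signal of each of 586 main peaks in one replicate against the other, both on log axes in the authors' signal units, with 1 point per peak and a grey line at equal signal; the list does not say which axis is which replicate. The strongest site stands at 371 and 413, far from the bulk around medians of 37.6 and 42.4, and the Spearman correlation is 0.105.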

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

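The peaks described here were looked at only because they were found missing from the main list, but the test of their sequence was set out before its result was seen. In the ranked list behind the main one, 115 peaks passed the IDR threshold and yet were absent from the authors' list, 16.3% of those that passed. The strongest of them, at X 15810949 to 15811191 in intergenic sequence, had a signal of 3701, against 783 for the strongest main peak, and 4 of them were stronger than every main peak. They drew attention as a strong signal outside the peaks that the comparisons used. Intergenic sequence held 106 of the 115 (92.2%), 90 lay within 5000 bases of another, and 77 and 69 of them overlapped a passing peak of replicates 1 and 2. None lay near a tRNA gene, and 2 lay near a ribosomal RNA gene.

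An excess of reads from sequences with many copies in the genome is a candidate explanation, and its test came out as it predicts. The median share of 31-base words found once in the genome was 5.29% around these summits, against 100% around main summits, and 87.8% of the 115 windows (interval 80.4 to 93.2) were repeat-masked over more than 50% of their length, against 13.8% of main windows (11.1 to 16.8) and 18.3% of failing ones. Filtering by the authors on a list of regions could then account for their absence, and the further file that the final lists derive from may be such a list, but what it holds is not given in the sources used here. The design has 1 group, so no biological explanation was tested, and binding of BED-1 at repeats stays open.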

How the results depend on the processing

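Tests with an IDR of 0.001, with the weaker of overlapping peaks dropped, with the 5000 strongest failing peaks (except for the promoter share), with unique windows, without peaks near non-coding RNA genes, and with correlations over signals above 100 or conservative peaks, and with other non-coding RNA genes counted only away from tRNA, snoRNA and snRNA genes, were chosen only after results were seen. The tRNA, snoRNA, snRNA and other non-coding RNA genes, the smaller share of coding exons and the higher GC content passed in every alternative run. Genes of microRNAs and piRNAs did not pass with replicate 2's list, at an IDR of 0.001 or against the 5000 strongest failing peaks, nor those of piRNAs with replicate 1's. Ribosomal RNA genes passed only with the peaks the authors left out kept (odds ratio 85.4). Each replicate left out means the other's own, shorter list, which has fewer peaks to test. The number of peaks was 91 to 99 with a replicate left out and 82 at an IDR of 0.001. Overlap of the replicates was 76.9% and 77.8% with the 1000 strongest ranked peaks. The correlation of replicate signal was 0.329 as Pearson's r of log2 signal, 0.252 across all ranked peaks, 0.162 across conservative peaks and 0.398 for signals over 100. The promoter odds ratio was 1.24 to 1.33 with a replicate left out and 1.58 at an IDR of 0.001 (exact test, p = 0.0769), and did not pass there. Classes past the test, 4 in the main analysis, were 2 at an IDR of 0.001: coding exons and intergenic sequence, which is not among the 4. With either replicate left out 3 passed, which were coding exons, non-coding genes and intergenic sequence; promoters and introns did not. In unique windows 3' UTRs passed in place of non-coding genes (odds ratio 1.96, exact test, adjusted p = 0.0154). Intergenic sequence, not past the main test, passed with odds ratios of 1.36 to 2.76 in 6 alternatives and turned to 0.890 in unique windows. The non-coding class turned to an odds ratio of 0.592 when peaks near non-coding RNA genes were left out, by construction. Chromosomes past the test, 1 in the main analysis, were 0 with the conservative list, with either replicate left out, at an IDR of 0.001, against the 5000 strongest failing peaks and in unique windows, and 2 (IV and V) without peaks near non-coding RNA genes. Gene lists past the test, 1 in the main analysis, were 0 to 1 with a replicate left out (0 with replicate 1's list), 0 against the 5000 strongest failing peaks and 2 without peaks near non-coding RNA genes; the odds ratio of ribosomal proteins was 10.6 to 28.3 and 3.33 in the former cases, and did not pass at 10.6 and 3.33. Motifs past the test, 1 in the main analysis, were 0 with the conservative list, a replicate left out, an IDR of 0.001 and windows of 50 or 200 bases, 2 with the peaks the authors left out or with unique windows, and 6 against all failing peaks, where neither class nor GC content was matched. Against the 5000 strongest failing peaks 1 passed, but it was CTGCGTCT and not TCGCGA (odds ratios 1.93 and 1.73). CTGCGTCT had an odds ratio of 0.762 to 1.45 with a replicate left out. The difference in signal between promoter and other peaks turned to -0.518 (conservative list), -2.72 (peaks the authors left out), -3.40 (IDR of 0.001) and -0.176 (weaker overlapping peaks dropped), and never passed. Words past the test, 2 in the main analysis, were 0 at an IDR of 0.001, with weaker peaks dropped, in unique windows and without peaks near non-coding RNA genes, 1 against the 5000 strongest failing peaks (AAGGATCA, exact test, adjusted p = 0.0488), 1 with words of 6 bases (AGCGCG), 7 with words of 10 bases and 20 with the chromosomes swapped. GAATTGAA and AAGGATCA were not among those 20. The outer parts of autosomes passed only without peaks near non-coding RNA genes (odds ratio 1.52). Except for the turn of the non-coding class, which is by construction, the cause was not tested. The unknown depth limits how far the lists of 91 and 99 peaks can be read.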

Other observations

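The comparisons of tRNA genes by chromosome and of summit positions, and the use of ribosomal protein genes as a test below, were chosen only after results were seen; the tests of sequence copies at tRNA genes and of overlapping peaks were set out before their results. The X chromosome, which carries 276 of the 612 tRNA genes, held most of the tRNA genes with a main summit. There, 45 of 276 (16.3%, 12.1 to 21.2) had one, against 27 of 336 on the autosomes (8.04%, 5.36 to 11.5; odds ratio 2.23, Fisher's exact test, p = 0.00230). Many tRNA genes on X are near-copies of each other, so their peaks are not independent. The position of the summit differed between kinds of gene. It lay before the first base of the RNA in 22 of 32 snoRNA genes (68.8%, 49.99 to 83.88), at a median of -29 bases, and in 27 of 72 tRNA genes (37.5%, 26.4 to 49.7), at a median of 12 bases (odds ratio 3.67, exact test, p = 0.00526). The 72 tRNA genes shared 63 peaks, many of them similar in sequence, and the 32 snoRNA genes shared 31. That p-value is therefore likely too small, and the difference is small beside the median peak width of 260 bases. Of all annotated genes, 32 snoRNA genes (9.25% of them) and 8 snRNA genes (6.20%) had a main summit.

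Similar sequence recurred among the strongest sites. Of the 589 main peaks, 166 were similar in sequence to another main peak, and 24 groups had 3 or more members. One group of 11, found after their values were seen, had 0 members at tRNA genes and a median signal of 130 (74.8 to 783). It held the strongest site at IV 4725567, the sites near rpa-2, mog-4 and C46C2.7, the one at II 4048036, and the rpl-7A promoter site, and 8 of the 11 were intergenic. The median unique share in the group was 51.2%, and its median masked share was 13.0%. Other strong sites lay in masked repeats. A group of 10, with median unique and masked shares of 11.2% and 100%, held X 1375275, IV 15896071 and the pck-2 site. A group of 5, with shares of 0% and 100%, held III 2497992 and III 2499478. The windows of these named sites were all masked over 100% of their length, and those of the other named sites over 0% to 32.0%.

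Reads shared between copies of a sequence are a candidate explanation for the tRNA sites, since tRNA genes are repeated. Among unique windows the odds ratio of tRNA genes was 8.58, though this rests on 5 main peaks. It cannot exclude read sharing at the genes themselves. A window reached 100 bases from the summit, while a tRNA gene counted as near could lie up to 200 bases away, outside the window. Among partly repeated windows, tRNA genes lay at 56 of 110 main peaks (50.9%) and 3.41% of failing peaks. The odds ratio there was 29.4 (Fisher's exact test, p = 7.4e-50). That value cannot decide the question, because the number of copies was not matched and read sharing between many copies could also raise it. How much of the effect at tRNA genes comes from copies is therefore not known. A strong signal at heavily transcribed genes of any kind stays open. The odds ratio of 10.8 for ribosomal protein genes had been seen when they were taken as its test, so it does not count in its favour. Other lists do not decide it: the odds ratio was 13.3 for vitellogenins, 2.58 for the proteasome, 1.91 for mitochondrial respiration and ribosome, 1.71 for histones and 1.24 for cuticle collagens, from 1 to 3 main genes each. None of them passed (Fisher's exact tests, adjusted p from 0.493 to 0.893). Other lists went the other way without passing. Major sperm proteins and intestine had 0 main genes, against 0.224% and 0.809% of background genes. How heavily the genes of any list were transcribed was not measured here. Binding of BED-1 at genes of the translation machinery is left open too. The list of translation factors and tRNA synthetases had 0 of 262 main genes (upper limit 1.40%) and 67 of 17420 background genes (0.385%). For that list, this argues against an enrichment as large as that of ribosomal proteins (3.82%, 1.85 to 6.91), but a smaller one cannot be told. No control or other factor was analysed here.

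Some main peaks were very weak. The main list held 12 peaks with a signal under the median of failing peaks, and all 12 overlapped a stronger main peak. In the 13 overlapping pairs the weaker peak had a signal of 2.43 to 24.1 and the stronger 42.7 to 103, and the weaker summit lay 201 to 212 bases to the right in all 13. A candidate explanation is that both pooled peaks were paired with the same peaks of the sets compared by IDR, so that the weaker took over the rank of the stronger. In 13 of the 13 pairs both members carried the same pair of compared peaks, which is what this explanation predicts. These weak peaks are therefore likely not separate sites, and leaving them out gave 576 peaks. Some of them were counted near non-coding RNA genes above, such as III 4015875 (signal 5.89) at a piRNA gene and X 10132889 (signal 8.02) at a tRNA gene. Another was II 5543721 to 5543980 (signal 24.1) at the snRNA gene sls-2.2.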
